A study of Mus musculus with 6 samples.

How the data were processed

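RNA was measured in 6 libraries of CD4+ T cells sorted from the spleens of C57BL/6 mice on postnatal day 28. The mice carried a reporter that makes cells transcribing the cytokine gene Il21 fluoresce with VFP. Cells were sorted on VFP and on the surface receptor ICOS, and each of 3 pools was sequenced as 2 libraries. The pool without VFP or ICOS is called N, the pool with ICOS alone ACT, and the pool with both ACT_IL21. Per the labels' protocols, RNA was extracted with Qiagen RNeasy kits, and polyadenylated RNA was reverse transcribed and amplified with the NuGEN Ovation kit. The sequencer was an Illumina MiSeq, per the series' design text.

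The values are gene-level TPM, transcript abundances scaled to a fixed total per library, deposited by the authors as 1 column per library. Trimmomatic, Bowtie, RSEM and the genome build GRCm38 were named without versions, per the submitters' processing notes. The annotation release, the read length and the strand setting are not given in the sources used here. RSEM divides reads that match several genes among them by estimation, so values of near-identical copies, pseudogenes and overlapping genes are uncertain. Because the total is fixed, a rise in abundant transcripts lowers the values of all others, and amplification of small RNA amounts can add noise to low values. TPM keeps no record of the number of reads. The depth of each library is therefore unknown, and no counting interval or detection floor is given.

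The table held 38355 gene entries with 38216 different symbols, and 139 entries with a repeated symbol were summed into their symbol. No mitochondrially encoded symbol was present in the table used here. Genes with at least 1 TPM in at least 2 of the 6 libraries were tested, which left 13311 genes. Of these, 11.22% were listed at 0 in at least 1 library. Because a 0 in a table of estimates has no known depth behind it, genes at 0 in both libraries of a pool are described as listed at 0, with library values and no fold against that pool.

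Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), without further scaling of the deposited TPM. All 6 libraries entered 1 linear model with a term for the pool, an empirical Bayes spread with an intensity trend, and two-sided tests. The model had 3 residual degrees of freedom and 4.841 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, separately in each of the 3 comparisons, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Levels are mean TPM ± SD over the 2 libraries of a pool. A moderated F test asked whether a gene differed among the 3 pools. Nothing in the labels says that the 2 libraries of a pool came from separate animals. The p-values therefore measure the spread between these libraries, which may be technical.

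Gene lists were tested with limma's camera, using a preset correlation of 0.01 between genes, for lists with at least 5 measured members. Adjustment was over the lists tested in a comparison. The lists were T cell core genes, T follicular helper, naive and quiescent T cell, T cell receptor response, effector and memory, coinhibitory and anergy, regulatory T cell, type 1 helper, type 2 helper, type 17 helper, cell cycle, glycolysis, interferon response, protein translation, dissociation and stress, and markers of B cells, natural killer and NKT cells, myeloid and dendritic cells and erythroid cells. The sort markers, the plasma cell list and the CD8 T cell list had too few measured members and are given as values. Some list members mark several cell types: Il4 is in the T follicular helper list and is also made by type 2 helper and NKT cells, and Klrg1, in the regulatory list, is also a natural killer cell receptor. Members were matched by exact symbol and counted past the threshold over all genes and adjusted over the list alone.

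The samples, tests, lists, alternatives and naming rule were set before the data were examined. Named genes were, in each comparison, the 10 with the largest and the 10 with the smallest log2 fold change past the threshold, with a mean of at least 5 TPM and no overlap between the pools. Provisional symbols, clone-type identifiers and receptor segments were left out of that part. The sort markers, up to 4 members of each list with the smallest p, and, where no member of a list passed, its most abundant member were named too. For the position of ACT, the 5 genes with the smallest F test p in each pattern were named, with no symbol left out. Genes named outside this rule are identified where they appear, and a few that it names are counted but not reported here.

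The comparisons of ACT and of ACT_IL21 with N use the same N libraries, which raises their overlap without any effect. That overlap was set against 50 simulations of unchanged pools and against independent lists. Alternatives changed the pseudocount, the filter on low values, the scaling, the spread estimate, the threshold, the libraries in the model, the replicate block, the list test and, with each library left out in turn, the replicates. Removing trends on transcript length or GC content and leaving out abundant genes were added after seeing the data. Length and GC content came from GENCODE M21 on GRCm38, which also gave the gene positions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

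The model was tested on data simulated with the real genes' means and the model's own spread estimate, the same in every pool. Each of 20 simulations per comparison had 200 changed genes among the 13311, drawn from those with a mean of at least 5 TPM. Recovery of lower genes was not measured. For ACT against N, the model recovered 43.5% of genes raised by 1 on the log2 scale and 92.4% of those raised by 2. It recovered 84.7% of those changed by -2. For ACT_IL21 against N, these shares were 42.4%, 92.5% and 85.4%. For ACT_IL21 against ACT, they were 43.9%, 93.4% and 83.2%. False calls made up 6.25%, 7.48% and 7.33% of the calls in these comparisons.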

Results

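Messenger RNA was profiled in CD4+ T cells from the spleens of 28-day-old mice that report transcription of Il21, the gene of a cytokine through which follicular helper T cells act on B cells. The cells were sorted into 3 pools by the reporter VFP and by ICOS, a costimulatory receptor that T cells raise on activation. N cells carried neither marker, ACT cells carried ICOS alone, and ACT_IL21 cells carried both. Each pool was measured in 2 libraries, as TPM with unknown depth. Each library had between 12095 and 12396 genes at 1 TPM or more. Libraries of the same pool were closer to each other than to any other library, with Spearman correlations across genes of 0.971 for N, 0.941 for ACT and 0.957 for ACT_IL21. Between pools these correlations ranged from 0.904 to 0.931, and genes are not independent replicates.

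The sort markers came first, since they check the labels and are no finding between the pools. Icos (chromosome 1, 60977927 to 61000320, GRCm38, plus strand, a protein-coding gene) was at 33.8 ± 2.65 TPM in N, 248 ± 9.02 in ACT and 206 ± 29.5 in ACT_IL21 (SD, n = 2). Il21 (chromosome 3, 37222759 to 37232636, minus strand, protein-coding) was listed at 0 in both N libraries, at 0 and 1.26 TPM in ACT, and at 44.48 and 51.87 TPM in ACT_IL21. Cd4 (chromosome 6, 124864692 to 124888221, minus strand, protein-coding), the coreceptor used for the sort, was at 337 ± 30 TPM in N, 252 ± 22.3 in ACT and 550 ± 23.3 in ACT_IL21. By limma, Icos rose against N in ACT (log2 fold change 2.84, adjusted p = 9.76e-05) and in ACT_IL21 (2.57, adjusted p = 0.00022), and did not pass between ACT_IL21 and ACT (-0.27, adjusted p = 0.493). Cd4 was higher in ACT_IL21 than in N (0.71, adjusted p = 0.0301) and than in ACT (1.13, adjusted p = 0.0103), and the value of ACT against N was -0.42 (adjusted p = 0.158).

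**Figure D1:**
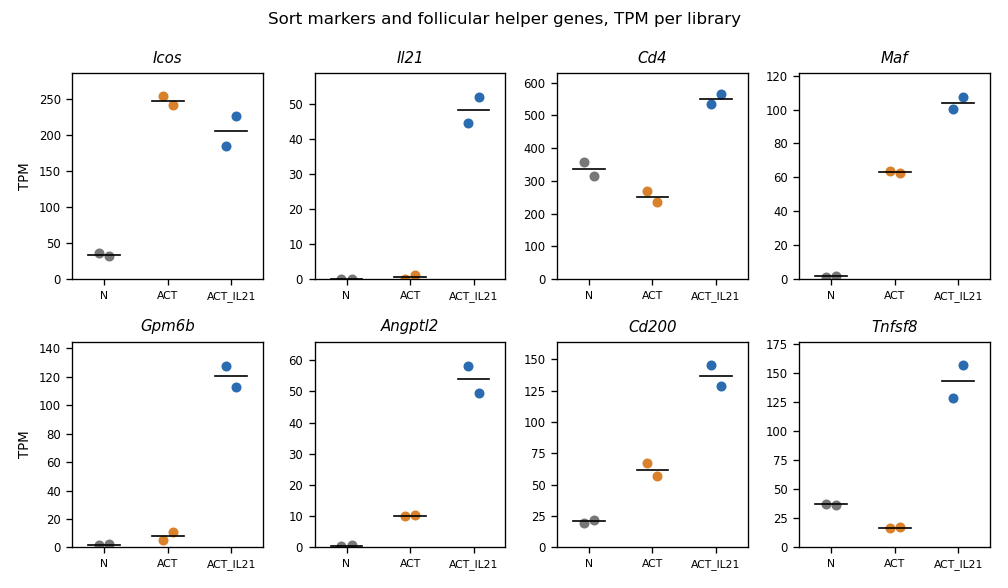
TPM per library (points) and pool mean (bars) of the sort markers Icos, Il21 and Cd4 and of 5 genes linked to follicular helper cells, on linear axes from 0. Gpm6b stood at 120 TPM on average in ACT_IL21 against 8.04 in ACT and 1.895 in N, and Tnfsf8 at 143 against 16.8 and 37.

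The comparison of ACT with N asks what separates ICOS+ cells without the reporter from ICOS- cells. ACT cells had lower RNA levels of genes of naive, recirculating T cells and higher levels of genes of memory, regulatory and polarized helper cells. Lef1, which encodes a transcription factor of naive T cells, fell from 404 ± 3.25 TPM in N to 117 ± 12.8 in ACT (SD, n = 2, log2 fold change -1.78 ± 0.15 SE, adjusted p = 0.000652). S100a4, a calcium-binding protein gene of memory T cells, rose from 5.6 ± 0.622 to 441 ± 78.8 TPM (6.06 ± 0.18, adjusted p = 1.21e-05). The chemokine receptor genes Ccr2, Cxcr3 and Cxcr6 rose by 6.74, 6.39 and 5.92 on the log2 scale, and Cxcr6 reached 562 ± 103 TPM.

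Of the 23 measured genes of the naive and quiescent T cell list, 17 fell, 1 rose and 5 did not pass, or 19 and 1 adjusted over the list alone. The naive list had a median of -1.45 (camera adjusted p = 5.16e-21, and adjusted p = 0.046 with an estimated correlation). S1pr1, the receptor that guides T cells out of lymphoid organs, fell from 500 ± 51.8 to 124 ± 7.59 TPM. The member that rose was Ccr9, a gut-homing receptor gene (2.77, adjusted p = 0.000642). In the effector and memory list, 15 of 20 genes rose and none fell, or 16 higher and 1 lower adjusted over the list alone. The effector and memory list had a median of 2.84 (adjusted p = 1.59e-20, and adjusted p = 0.0269 with an estimated correlation). S100a6 rose from 1.005 ± 0.0636 to 159 ± 52.8 TPM, and Id2, a transcriptional regulator gene of effector cells, from 52.8 ± 2.94 to 777 ± 118 TPM.

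Lists of polarized and regulatory cells rose together in ACT. In the type 1 helper list 11 of 16 genes rose, or 13 adjusted over the list alone. The type 1 list had a median of 2.74 (adjusted p = 1.96e-16, and adjusted p = 0.0269 with an estimated correlation). Nkg7, a cytotoxic granule gene, was at 469 ± 99.2 TPM against 8.45 ± 0.636 in N, and the chemokine gene Ccl5 at 329 ± 106 against 14.9 ± 1.8. In the type 2 helper list 5 of 7 rose, or 6 higher and 1 lower adjusted over the list alone. The type 2 list had a median of 2.93 (adjusted p = 6.12e-06, and adjusted p = 0.0438 with an estimated correlation). Ccr4 (5.51) and Gata3, the lineage transcription factor gene (1.14), were among those that rose. With any single library left out Gata3 lost its call, at log2 fold changes of 1.01 to 1.27, while Ccr4 kept it. In the type 17 helper list 5 of 9 rose, or 7 adjusted over the list alone. The type 17 list had a median of 2.32 (adjusted p = 2.8e-07, and adjusted p = 0.0368 with an estimated correlation). Rora, which encodes a nuclear receptor, was at 97.8 ± 3.93 TPM against 7.265 ± 0.898 in N. The regulatory T cell list had 13 of 17 genes higher and none lower, or 14 adjusted over the list alone. The regulatory list had a median of 2.3 (adjusted p = 1.66e-14, and adjusted p = 0.0306 with an estimated correlation). Its members Ikzf2, which encodes the transcription factor Helios, and Ctla4, an inhibitory receptor gene, rose by 2.98 and 2.64 on the log2 scale.

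The T follicular helper list had 12 of 29 genes higher and 3 lower in ACT, the same counts adjusted over the list alone. The follicular list had a median of 0.37 (adjusted p = 7.47e-05, and adjusted p = 0.0438 with an estimated correlation). Maf, a transcription factor gene that drives Il4 and Il21, rose from 1.44 ± 0.283 to 63.4 ± 0.799 TPM, and Il4 from 0.255 ± 0.361 to 76 ± 20.7 TPM. The cell cycle list had 8 of 32 genes higher, or 17 adjusted over the list alone. The cell cycle list had a median of 1.35 (adjusted p = 1.25e-09, and adjusted p = 0.0306 with an estimated correlation). The proliferation marker gene Mki67 rose from 3.3 ± 1.02 to 36.6 ± 2.7 TPM.

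Markers of natural killer and NKT cells moved with these lists. Of 12 such genes 7 rose in ACT, or 8 adjusted over the list alone. This natural killer list had a median of 2.43 (adjusted p = 6.99e-09, and adjusted p = 0.0306 with an estimated correlation). Klrb1c, which encodes the NK1.1 antigen, rose from 2.47 ± 0.127 to 172 ± 7.93 TPM, and the chemokine gene Xcl1 from 2.07 ± 0.0141 to 212 ± 23.3 TPM. Zbtb16 (chromosome 9, 48654297 to 48836222, minus strand, protein-coding), which encodes PLZF, a transcription factor of innate-like T cells, rose from 0.09 ± 0.127 to 33.7 ± 9.01 TPM. Klrg1, counted in the regulatory list and also a natural killer cell receptor gene, rose by 5.75 on the log2 scale. The Klr genes are members of a family of similar sequence, and their values are uncertain to that extent. Whether natural killer or NKT cells in ACT also raised the helper, memory and regulatory lists was not tested.

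Other lists passed camera in ACT against N without passing when the correlation was estimated. The estimate was -0.0752 for coinhibitory genes, below the preset 0.01, and above it for the rest, at 0.039 to 0.15. Correlation between members therefore did not end the coinhibitory call. T cell receptor response had 6 of 20 genes higher, or 8 higher and 1 lower adjusted over the list alone. The receptor response list had a median of 0.45 (adjusted p = 0.00189, but adjusted p = 0.127 with an estimated correlation). Bhlhe40, a transcription factor gene of activated T cells, rose by 4.86 on the log2 scale. Coinhibitory and anergy genes had 5 of 13 higher and 1 lower, or 7 and 2 adjusted over the list alone. The coinhibitory list had a median of 1.53 (adjusted p = 0.0012, but adjusted p = 0.069 with an estimated correlation). Tigit, an inhibitory receptor gene, rose by 5.07, and Dgka, a diacylglycerol kinase gene, fell by 1.45 on the log2 scale. Glycolysis had 4 of 17 higher and 1 lower, or 6 and 1 adjusted over the list alone. The glycolysis list had a median of 0.38 (adjusted p = 0.00203, but adjusted p = 0.213 with an estimated correlation). Slc2a3, a glucose transporter gene, rose (1.4), and Pdk1, a pyruvate dehydrogenase kinase gene, fell (-1.54). Interferon response had 3 of 24 higher, Rsad2, Mx1 and Oas1a, or 4 adjusted over the list alone. Each of these named genes lost its call with any single library left out. The interferon list had a median of 0.45 (adjusted p = 0.00401, but adjusted p = 0.167 with an estimated correlation, and adjusted p = 0.0744 without ACT replicate 1). In the B cell list 1 of 6 rose, or 2 adjusted over the list alone. The B cell list had a median of 1.05 (adjusted p = 0.0155, but adjusted p = 0.193 with an estimated correlation). The B cell call also ended without N replicate 2 (adjusted p = 0.0748), without ACT replicate 2 (0.121), after rescaling without ribosomal and receptor genes (0.111) and without a filter on low values (0.463, median -0.02). Cd74, the invariant chain gene of antigen-presenting cells, rose from 2.61 ± 0.679 to 16.2 ± 2.26 TPM.

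Lists that did not pass in ACT against N were T cell core genes (0 higher and 1 lower of 14, 0 and 2 adjusted over the list alone, median 0.09, adjusted p = 0.768), protein translation (0 of 18 in either count, median -0.02, adjusted p = 0.225, but 0.0497 without N replicate 1) and dissociation and stress (1 higher and 2 lower of 17, 4 and 2 adjusted over the list alone, median 0.05, adjusted p = 0.913). The immediate early genes Jun and Fos fell (-1.18 and -0.74), and the phosphatase gene Dusp1 rose (1.22). Erythroid cell genes did not pass either (0 of 9 in either count, median 0.07, adjusted p = 0.996). The myeloid and dendritic cell list had 1 of 5 higher, Cst3 (1.01), or 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.996), and its median of -0.37 had the opposite sign to the direction of the test fry. Xbp1, the measured plasma cell gene, was at 80.7 ± 13.2 TPM in N and 108 ± 33.9 in ACT, and Cd8b1, the measured CD8 T cell gene, at 22.7 ± 5.62 and 6.5 ± 1.29, neither past the threshold.

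Across the 13311 genes tested, limma placed 553 genes higher and 190 lower in ACT than in N, 743 in all (5.58%), of which 493 and 146 differed by more than 2-fold. The largest falls among named genes were of Slc16a5, a monocarboxylate transporter family gene (-3.91), the cytoskeletal gene Pdlim4 (-3.51), the pseudogene Bambi-ps1 (-3.12, uncertain against its parent gene), Amigo2 (-3.05) and Rnf32 (-3.04). The count was 205 without N replicate 1, 225 without N replicate 2, 398 without ACT replicate 1, 400 and 401 without ACT_IL21 replicates 1 and 2, 417 with the ACT and N libraries alone, and 469 without a filter on low values. S1pr1, Lef1, S100a4, S100a6, Ccr2, Cxcr3, Cxcr6, Id2, Maf, Il4, Klrb1c, Xcl1, Zbtb16, Mki67, Ikzf2 and Ctla4 were among the 41 of 69 named genes that passed with each of the 6 libraries left out. Calls of named genes ended for 28 without N replicate 1, 27 without N replicate 2, 15 and 10 without ACT replicates 1 and 2, and 13 each without ACT_IL21 replicates 1 and 2 (adjusted p up to 0.324).

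**Figure D2:**
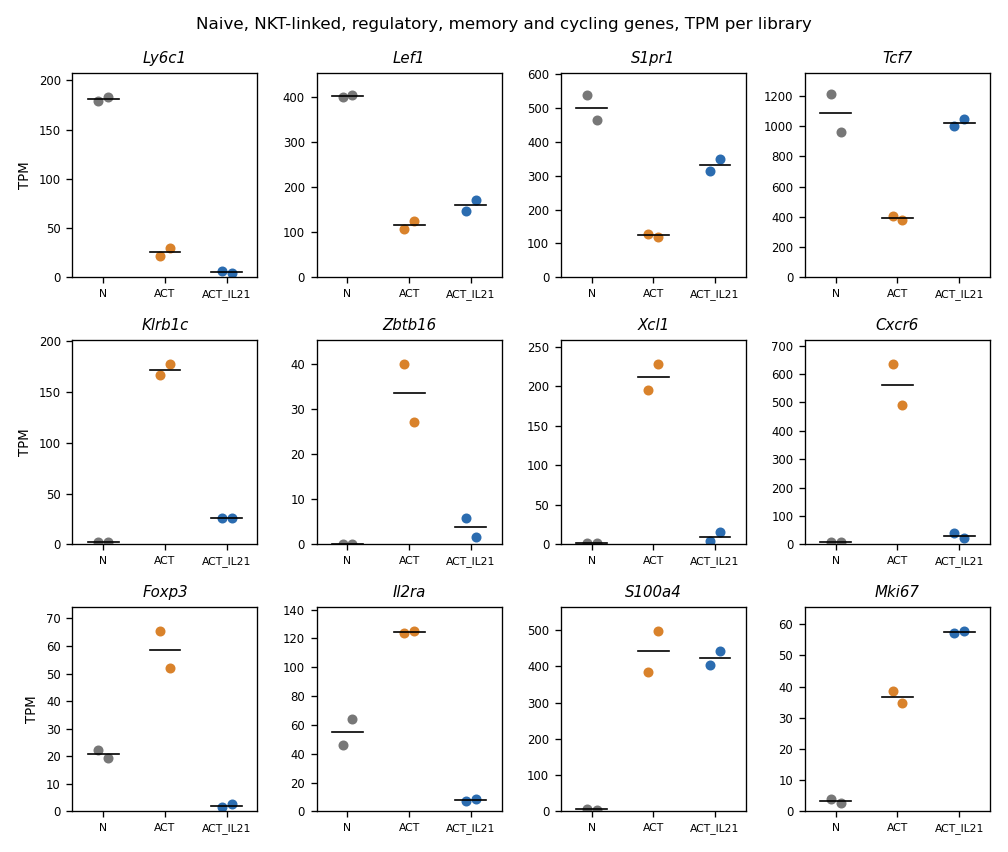
TPM per library (points) and pool mean (bars) of naive, NKT-linked, regulatory, memory and cycling genes, on linear axes from 0. Klrb1c, Zbtb16, Xcl1 and Cxcr6 were highest in both ACT libraries, Foxp3 averaged 58.6 TPM in ACT and 2.13 in ACT_IL21, and Tcf7 averaged 394 in ACT against 1085 in N and 1022 in ACT_IL21.

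The comparison of ACT_IL21 with N covers both sort markers. ACT_IL21 cells had higher RNA levels of follicular helper genes in addition to memory genes. Of 29 T follicular helper genes 20 rose and none fell, or 23 adjusted over the list alone. The follicular list had a median of 1.86 (camera adjusted p = 9.35e-21, and adjusted p = 0.0159 with an estimated correlation). Maf rose from 1.44 ± 0.283 TPM in N to 104 ± 4.91 in ACT_IL21 (SD, n = 2, log2 fold change 5.43 ± 0.23 SE, adjusted p = 4.7e-05), and Gpm6b, a membrane glycoprotein gene, from 1.895 ± 0.318 to 120 ± 10.5 TPM (5.39 ± 0.35, adjusted p = 0.000256). Tox2, which encodes a transcription factor of follicular helper cells, was listed at 0 in both N libraries and stood at 27.34 and 29.21 TPM in ACT_IL21. Cd200, an immunoglobulin superfamily surface glycoprotein gene, rose from 20.8 ± 1.96 to 137 ± 12.2 TPM.

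In the effector and memory list 14 of 20 genes rose, or 16 adjusted over the list alone. The effector and memory list had a median of 1.99 (adjusted p = 4.88e-22, and adjusted p = 0.0159 with an estimated correlation). S100a6 was at 207 ± 17.7 TPM and S100a4 at 422 ± 28 TPM in ACT_IL21, and the integrin gene Itgb1 rose from 31.1 ± 5.73 to 575 ± 108 TPM. The type 1 helper list had 10 of 16 genes higher, or 12 adjusted over the list alone. The type 1 list had a median of 2.07 (adjusted p = 4.09e-13, and adjusted p = 0.0193 with an estimated correlation). Cxcr3 (5.79) and the interferon-gamma gene Ifng (4.72) rose. The type 17 helper list had 5 of 9 higher, or 8 adjusted over the list alone. The type 17 list had a median of 2.44 (adjusted p = 2.23e-07, and adjusted p = 0.0427 with an estimated correlation). Rora (2.51) and the aryl hydrocarbon receptor gene Ahr (2.44) rose. In the cell cycle list 12 of 32 rose, or 21 adjusted over the list alone. The cell cycle list had a median of 1.5 (adjusted p = 1.31e-12, and adjusted p = 0.0193 with an estimated correlation). Mki67 reached 57.5 ± 0.537 TPM.

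The naive and quiescent T cell list had 12 of 23 genes lower and none higher, or 16 adjusted over the list alone. The naive list had a median of -0.78 (adjusted p = 5.28e-19, but adjusted p = 0.0613 with an estimated correlation). Ly6c1, a surface antigen gene, fell from 181 ± 3.2 to 5.355 ± 1.76 TPM, and Bach2, a transcriptional repressor gene, from 113 ± 2.72 to 32.3 ± 0.919 TPM. The regulatory T cell list was split, with 6 of 17 higher and 4 lower, or 8 and 5 adjusted over the list alone (median 0.7, adjusted p = 0.251). Foxp3 (chromosome X, 7573644 to 7595245, plus strand, protein-coding), the lineage transcription factor gene of regulatory T cells, fell by 2.82 on the log2 scale (adjusted p = 0.00251), and Il2ra, the gene of the interleukin-2 receptor alpha chain, by 2.66 (adjusted p = 0.000816), while Nrp1 and Ctla4 rose (2.61 and 2.7).

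Other lists passed camera here but not with an estimated correlation. The estimate was -0.0752 for coinhibitory genes, -0.105 for type 2 and -0.0132 for translation, below the preset 0.01. Correlation between members therefore did not end the calls of these lists. The follicular list, with an estimate of -0.00503, likewise went from a camera adjusted p = 9.35e-21 to 0.0159. Camera p-values with an estimated correlation therefore reflect more than correlation between members, and what else sets them was not tested. Coinhibitory and anergy genes had 5 of 13 higher, or 8 higher and 2 lower adjusted over the list alone. The coinhibitory list had a median of 1.66 (adjusted p = 0.000167, but adjusted p = 0.0613 with an estimated correlation). Tigit (5.33) and the ectonucleotidase gene Nt5e (2.41) rose. T cell receptor response had 3 of 20 higher, Bhlhe40, Nfatc1 and Egr2, and 1 lower, Myc, or 7 and 1 adjusted over the list alone. The receptor response list had a median of 0.46 (adjusted p = 0.00712, but adjusted p = 0.178 with an estimated correlation). Glycolysis had 4 of 17 higher and 1 lower, Pdk1, or 5 and 1 adjusted over the list alone. The glycolysis list had a median of 0.47 (adjusted p = 0.0111, but adjusted p = 0.307 with an estimated correlation). The type 2 helper list had 1 of 7 higher, Ccr4 (5.46), and 1 lower, Il4ra (-1.82), or 4 and 1 adjusted over the list alone. The type 2 list had a median of 0.95 (adjusted p = 0.0132, but adjusted p = 0.154 with an estimated correlation, 0.0532 without ACT_IL21 replicate 2 and 0.0652 without a filter on low values). Protein translation had 2 of 18 lower, Eef1g and Eef1b2, in either count, the second adjusted over the list alone. The translation list had a median of -0.31 against 0.0996 over all genes (adjusted p = 1.52e-05, but adjusted p = 0.0511 with an estimated correlation). T cell core genes had 1 higher, Cd28, and 1 lower of 14, or 5 higher and 1 lower adjusted over the list alone. The T cell core list had a median of 0.39 (adjusted p = 0.00753, but adjusted p = 0.307 with an estimated correlation and 0.0501 without ACT_IL21 replicate 2). Dissociation and stress genes had 1 of 17 higher, the immediate early gene Fosb (2.59), or 4 higher and 1 lower adjusted over the list alone. The stress list had a median of 0.44 (adjusted p = 0.0214, but adjusted p = 0.307 with an estimated correlation). The stress call also ended without N replicate 2 (adjusted p = 0.0528), without ACT_IL21 replicate 2 (0.122) and with a mean TPM of at least 10 (0.215).

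Among markers of other cells, Cd22, a B cell receptor modulator gene, was higher in ACT_IL21 at 15.3 ± 3.08 TPM against 0.035 ± 0.0495 in N, while the B cell list as a whole did not pass (1 of 6 higher in either count, the second adjusted over the list alone, median 0.56, adjusted p = 0.251). Natural killer and NKT cell genes had 2 of 12 higher, Klrb1c and Gzmb, and 2 lower, Klrd1 and Prf1, or 4 and 2 adjusted over the list alone (median 0.07, adjusted p = 0.61). Interferon response (1 higher and 2 lower of 24, 2 and 3 adjusted over the list alone, median -0.03, adjusted p = 0.16), myeloid and dendritic cell genes (0 of 5, 1 higher adjusted over the list alone, median -0.46, adjusted p = 0.24) and erythroid cell genes (0 of 9, 1 higher adjusted over the list alone, median 0.94, adjusted p = 0.0786) did not pass. The erythroid list passed at the preset correlation without N replicate 1 (median 1.7) and without ACT_IL21 replicate 2 (median 1.68). Its estimated correlation was 0.679, with which camera gave adjusted p = 0.521 on all 6 libraries. Xbp1 was at 114 ± 18.7 TPM and Cd8b1 at 6.605 ± 4.52 TPM in ACT_IL21, neither past the threshold against N.

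By limma 509 genes were higher and 168 lower in ACT_IL21 than in N, 677 in all (5.09%), of which 450 and 128 differed by more than 2-fold. Named genes with large falls included Igfbp4 (-3.58), the flippase gene Atp8b4 (-3.51) and Tlr7, the gene of an endosomal RNA sensor (-3.46). The count was 128 without N replicate 1, 124 without N replicate 2, 79 and 75 without ACT_IL21 replicates 1 and 2, and 410 without a filter on low values. Maf, Gpm6b, Tox2, Cd200, S100a4, S100a6, Itgb1, Cxcr3, Mki67, Ly6c1, Bach2 and Il2ra were among the 33 of 73 named genes that passed with each of the 6 libraries left out. Calls of named genes ended for 33 and 35 without N replicates 1 and 2 and for 35 and 36 without ACT_IL21 replicates 1 and 2 (adjusted p up to 0.354).

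The comparison of ACT_IL21 with ACT asks what goes with the Il21 reporter among ICOS+ cells. ACT_IL21 cells had higher levels of follicular helper genes and lower levels of regulatory T cell and NKT-linked genes. Gpm6b rose from 8.04 ± 3.66 TPM in ACT to 120 ± 10.5 in ACT_IL21 (SD, n = 2, log2 fold change 3.8 ± 0.35 SE, adjusted p = 0.00367), and Tnfsf8, which encodes the ligand of CD30, from 16.8 ± 0.566 to 143 ± 20.2 TPM (3.01 ± 0.19, adjusted p = 0.0019). Foxp3 fell from 58.6 ± 9.59 to 2.13 ± 0.792 TPM (-4.27 ± 0.31, adjusted p = 0.00212), and Il2ra from 124 ± 1.32 to 7.82 ± 0.933 TPM (-3.83 ± 0.23, adjusted p = 0.0019). For both genes the N level lay between, at 20.8 ± 1.99 and 55.2 ± 12.8 TPM.

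The T follicular helper list had 12 of 29 genes higher and 1 lower, Il4 (-2.38), or 20 and 1 adjusted over the list alone. The follicular list had a median of 1.21 (camera adjusted p = 1.06e-13, and adjusted p = 0.0385 with an estimated correlation). Slamf6, which encodes an adhesion receptor used in contacts with B cells, rose from 117 ± 10.8 to 331 ± 18.8 TPM, and Tox2 stood at 3.53 and 3.24 TPM in ACT and at 27.34 and 29.21 TPM in ACT_IL21. Sostdc1, a secreted antagonist of BMP and Wnt signals, was listed at 0 in the N and ACT libraries and stood at 18.48 and 33.8 TPM in ACT_IL21. The protease inhibitor gene Stfa3 was likewise listed at 0 there and stood at 33.88 and 15.09 TPM, and the pseudogene Rpl30-ps10 at 9.03 and 21.15 TPM. Reads of Stfa3, Rpl30-ps10 and H2-Q2 (29.4 ± 12 TPM in ACT_IL21, 1.78 ± 2.52 in ACT) can match near-identical copies, which leaves these values uncertain.

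The regulatory T cell list had 7 of 17 genes lower and none higher, or 9 adjusted over the list alone. The regulatory list had a median of -1.23 (adjusted p = 1.06e-13, and adjusted p = 0.0496 with an estimated correlation). The integrin gene Itgae fell from 22.5 ± 5.49 to 0.945 ± 0.445 TPM, and Klrg1 from 85.4 ± 17.8 to 2.78 ± 0.113 TPM. Natural killer and NKT cell genes moved in the same direction, with 7 of 12 lower and none higher, or 11 adjusted over the list alone. This natural killer list had a median of -2.52 (adjusted p = 1.83e-13, and adjusted p = 0.0385 with an estimated correlation). Klrb1c fell from 172 ± 7.93 to 25.6 ± 0.148 TPM, Xcl1 from 212 ± 23.3 to 9.75 ± 8.29 TPM, and Klrd1, a receptor chain gene of natural killer cells, from 87.2 ± 1.84 to 10.1 ± 5.27 TPM.

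The type 1 and type 2 helper, interferon and translation lists were lower in ACT_IL21 by camera but did not pass when the correlation was estimated. The estimate was -0.0113 for type 1, -0.105 for type 2 and -0.0132 for translation, below the preset 0.01, and 0.0477 for interferon. Correlation between members therefore did not end the type 1, type 2 and translation calls. The type 1 helper list had 3 of 16 lower, Il12rb2 and Nkg7 among them, or 3 higher and 8 lower adjusted over the list alone. The type 1 list had a median of -0.64 (adjusted p = 1.05e-05, but adjusted p = 0.072 with an estimated correlation). The type 2 helper list had 2 of 7 lower, Il17rb and Ccr8, or 4 adjusted over the list alone. The type 2 list had a median of -1.01 (adjusted p = 6.63e-05, but adjusted p = 0.075 with an estimated correlation). Interferon response had 0 of 24 past the threshold, or 5 lower adjusted over the list alone. The interferon list had a median of -0.55 (adjusted p = 7.42e-07, but adjusted p = 0.075 with an estimated correlation). Protein translation had 0 of 18, or 1 lower adjusted over the list alone. The translation list had a median of -0.21 (adjusted p = 0.000379, but adjusted p = 0.075 with an estimated correlation).

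The naive and quiescent T cell list had 7 of 23 higher and 3 lower, or 10 and 5 adjusted over the list alone. The naive list had a median of 0.26 (adjusted p = 0.0442, but adjusted p = 0.534 with an estimated correlation). Tcf7, a transcription factor gene of naive and follicular helper cells, rose from 394 ± 21.4 to 1022 ± 34.6 TPM, S1pr1 rose from 124 ± 7.59 to 331 ± 25.4 TPM, and Il7r, the interleukin-7 receptor gene, fell from 500 ± 69.2 to 188 ± 23.9 TPM. The naive list call ended without ACT replicate 2 (adjusted p = 0.212), ACT_IL21 replicate 1 (0.095) or ACT_IL21 replicate 2 (0.148), and with a mean TPM of at least 10 (0.0534). T cell core genes had Cd247, the gene of the CD3 zeta chain, higher (0.94) of 14, or 3 adjusted over the list alone. The T cell core list had a median of 0.26 (adjusted p = 0.00931, but adjusted p = 0.37 with an estimated correlation, 0.212 without ACT replicate 2 and 0.0574 without ACT_IL21 replicate 2). The cell cycle list had 0 of 32 past the threshold, or 2 higher adjusted over the list alone. The cell cycle list had a median of 0.34 (adjusted p = 0.0442, but adjusted p = 0.201 with an estimated correlation, which was only 0.000373). That call ended without ACT replicate 1 (0.0515), ACT replicate 2 (0.212) or ACT_IL21 replicate 1 (0.181), and with a pseudocount of 0.1 (0.0558). Dissociation and stress genes had 1 of 17 higher, Fos (1.2), or 4 adjusted over the list alone. The stress list had a median of 0.33 (adjusted p = 0.0442, but adjusted p = 0.392 with an estimated correlation). The stress call ended without ACT replicate 2 (adjusted p = 0.212) or ACT_IL21 replicate 2 (0.192) and with a mean TPM of at least 10 (0.0663).

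Lists that did not pass between ACT_IL21 and ACT included T cell receptor response (0 higher and 3 lower of 20, 5 and 5 adjusted over the list alone, median -0.02, adjusted p = 0.509), in which Tnfrsf9, Spry2 and Bhlhe40 fell. Effector and memory genes had 2 of 20 higher and 4 lower, or 6 and 5 adjusted over the list alone (adjusted p = 0.861), with a median of 0.3 and a mean of -0.24. In that list Id2 fell from 777 ± 118 to 185 ± 36.1 TPM, and Itga4, an integrin gene, rose from 221 ± 42.3 to 600 ± 58 TPM. Coinhibitory and anergy genes (1 higher, Dgka, and 1 lower, Cd160, of 13, 3 and 1 adjusted over the list alone, median 0.26, adjusted p = 0.127) and glycolysis (1 lower of 17, Slc2a3, in either count, the second adjusted over the list alone, median -0.02, adjusted p = 0.815) did not pass. The type 17 helper list had 0 of 9 past the threshold, or 1 lower adjusted over the list alone (adjusted p = 0.723), and its median of 0.01 and mean of 0.1 differed in sign from camera's direction. The B cell list had 0 of 6, or 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.28), with a median of -0.65 and a mean of 0.01. Cd22 was at 2.65 ± 1.46 TPM in ACT and 15.3 ± 3.08 in ACT_IL21 (adjusted p = 0.0639). Myeloid and dendritic cell genes (0 of 5, 1 lower adjusted over the list alone, median -0.13, adjusted p = 0.25) and erythroid cell genes (0 of 9, 1 higher adjusted over the list alone, median 0.87, adjusted p = 0.0568) did not pass, nor did Xbp1 (0.09) and Cd8b1 (-0.11). The erythroid list passed at the preset correlation without N replicate 1, N replicate 2 or ACT_IL21 replicate 2 (median 1.73 in the last). With its estimated correlation of 0.679, camera gave adjusted p = 0.574 on all 6 libraries.

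**Figure D3:**
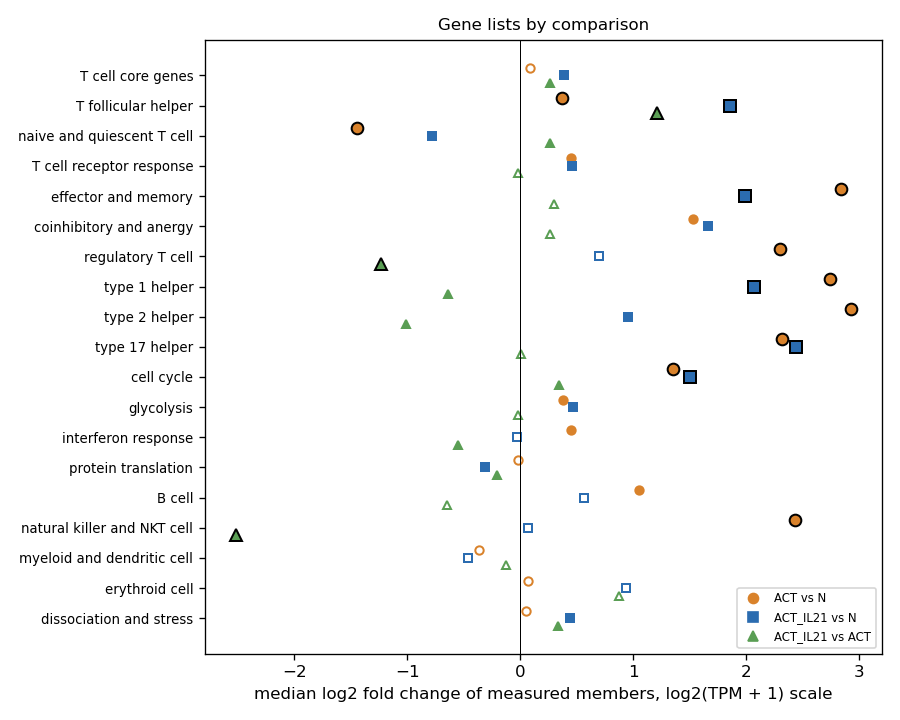
Median log2 fold change of the measured members of each gene list (horizontal axis, log2(TPM + 1) scale) in the 3 comparisons. Filled symbols passed camera with the preset correlation and black-edged larger symbols also with an estimated one, as did the T follicular helper list at 0.37, 1.86 and 1.21.

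By limma 106 genes were higher and 153 lower in ACT_IL21 than in ACT, 259 in all (1.95%), of which 95 and 147 differed by more than 2-fold. Further named genes that fell included the water channel gene Aqp9 (-4.65), Cxcr6 (-4.2), the fatty acid transporter gene Slc27a6 (-4.07), Atp8a2 (-3.94) and Klrk1 (-3.84). None of the 259 calls held with every library left out: limma called 0 genes without ACT_IL21 replicate 1 (1631 at an unadjusted p under 0.05), 5 without ACT_IL21 replicate 2, 35 and 81 without ACT replicates 1 and 2, and 76 and 74 without N replicates 1 and 2. The count was 92 with the ACT and ACT_IL21 libraries alone and 124 without a filter on low values. Leaving out a library also lowers the residual degrees of freedom, so a call can end without a change in effect. Without either N library, which this comparison does not use, Klrk1 kept its log2 fold change of -3.84 but lost its call. Of the 45 named calls, 45 and 40 ended without ACT_IL21 replicates 1 and 2 (adjusted p up to 0.289), 29 and 19 without ACT replicates 1 and 2, and 16 each without N replicates 1 and 2.

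The pools can be ordered by their sort markers, and the position of ACT between N and ACT_IL21 was described for the 936 genes that differed among the 3 pools by the F test. In 312 genes the ACT mean lay between and rose toward ACT_IL21, as for S100a6, Maf, Tigit, the adhesion receptor gene Cd44 (24.6 ± 3.3 TPM in N, 214 ± 9.72 in ACT and 220 ± 20.7 in ACT_IL21) and Prr13. In 72 genes it lay between and fell, as for Ly6c1 (181, 25.4 and 5.355 TPM), Igfbp4, the GTPase gene Tgtp1, Rnf130 and St8sia6. ACT had the highest mean in 381 genes, among them S100a4, Ccr4, Klrb1c, Nkg7 and the survival gene Bcl2a1d (5.36 ± 1.47, 176 ± 6.31 and 126 ± 5.08 TPM), and the lowest in 171, among them Tnfsf8, S1pr1, Lef1 and Gm11346. Tgtp1 and Bcl2a1d have near-identical neighbours. A mean outside the other two does not show a difference from both: calls of ACT against N and of ACT_IL21 against ACT were both made in 106 of the 381 genes and 44 of the 171, and in 8 of the 312 and 2 of the 72. The F test called 227 and 228 genes without N replicates 1 and 2, 278 and 284 without ACT_IL21 replicates 1 and 2, and 573 without a filter on low values. In the same order, the 384 genes with ACT between became 73, 75, 79, 84 and 236, and the 552 with ACT outside became 154, 153, 199, 200 and 337.

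ACT and ACT_IL21 shared 354 calls against N in the same direction, 293 higher and 61 lower, and 4 in opposite directions. Memory and helper genes such as S100a4, S100a6, Cxcr3, Ccr4, Maf and Tigit were among those higher in both, and Lef1, Ly6c1 and Igfbp4 among those lower in both. Independent lists of the same sizes would share 21.1 higher and 2.4 lower genes, and 50 simulations of unchanged pools against the same N libraries shared a median of 0 and at most 1. The simulations leave out the effects and the independent lists leave out the shared N libraries. The correlation of the fold changes across genes was 0.615 against 0.502 simulated, and their covariance 0.385 against 0.0895, a difference of 0.295. The 2 N libraries were not split between the comparisons, and part of the excess may come from sharing them. The number of shared calls was 85 and 93 without N replicates 1 and 2, 60 without either ACT_IL21 replicate, and 215 without a filter on low values.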

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

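Removing length or GC trends and leaving out the abundant genes were alternatives chosen after seeing the data. None of the 187 named results past the threshold reversed under any alternative, and across 747 such results under other scalings 0 changed sign and 11 lost their call. Of the 187, calls ended for 37 with no intensity trend, 36 without a filter on low values, 24 with the libraries of the compared pools alone, 11 with a pseudocount of 0.1, 3 with a pseudocount of 5, 4 with sample weights, 1 with the replicate block, and 1 each with the length trend removed without and with that block. With single libraries left out, 113 of the 187 ended at least once. Quantile normalization moved the median log2 fold change of all genes by -0.152 in ACT_IL21 against N. No called list changed sign under another scaling, and the only list call that a scaling ended was that of B cell genes in ACT against N (median 0.34, adjusted p = 0.111). The erythroid list, which did not pass, gained calls with median-of-ratios scaling (adjusted p = 0.0391 in ACT_IL21 against N and 0.0437 in ACT_IL21 against ACT) and quantile normalization (0.0378 and 0.0495), and also without a filter on low values (0.0405, against N) and with a pseudocount of 5 (0.0388, against ACT). Removing the length trend, leaving out the abundant genes, a robust spread, other pseudocounts and a mean TPM of at least 10 kept each count of genes within 1.5 times. With a replicate block the counts were 784 for ACT against N, 732 for ACT_IL21 against N and 284 for ACT_IL21 against ACT, of which 699, 643 and 246 were the genes called without it, and the erythroid list passed in ACT_IL21 against N (adjusted p = 0.00283) and against ACT (0.00206). The labels do not say that equal replicate numbers form a block, and across the genes tested the differences between replicates 1 and 2 correlated at 0.21 for N and ACT, -0.004 for N and ACT_IL21 and 0.000782 for ACT and ACT_IL21.

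Without a filter on low values, which adds low genes to the adjustment, ACT against N had 469 genes (341 higher and 128 lower), ACT_IL21 against N 410 (321 higher and 89 lower), ACT_IL21 against ACT 124 (43 and 81) and the F test 573. ACT then lay between in 236 genes and outside in 337, and 215 calls were shared. With an adjusted p under 0.10 the counts were 1187 (835 and 352), 1061 (786 and 275), 533 (272 and 261) and 1480. With the libraries of the compared pools alone, ACT against N had 417 (313 and 104) and ACT_IL21 against ACT 92 (26 and 66), while ACT_IL21 against N had 715 (536 and 179). With no intensity trend, 105 genes were lower in ACT_IL21 than in N and 59 higher than in ACT. With sample weights 256 genes were lower in ACT_IL21 than in N, and with the GC trend removed 181 were higher than in ACT. For these settings of libraries, spread and GC the cause was not tested. Replicate differences were widest in ACT, with an SD across genes of 0.5484 in N, 0.7868 in ACT and 0.6787 in ACT_IL21. The model with all 6 libraries gives the pools 1 shared spread, and its counts for comparisons with ACT rest on that. With an estimated correlation 9, 5 and 3 lists passed in place of 14, 13 and 11, and fry called 15, 14 and 9. Fry called the myeloid list higher in ACT than in N (adjusted p = 0.00676) although its median was -0.37, and camera did not call it (adjusted p = 0.996). Fry also called that list lower in ACT_IL21 than in N (0.00672) and in ACT (0.00362), and added calls of B cell genes (0.0474) and natural killer and NKT cell genes (0.0256) in ACT_IL21 against N and of coinhibitory genes in ACT_IL21 against ACT (0.0196). It ended the calls of glycolysis (0.081) and stress genes (0.0533) in ACT_IL21 against N, and of naive (0.182), T cell core (0.0904), cell cycle (0.0576) and stress genes (0.0916) in ACT_IL21 against ACT. Removing the GC trend ended the calls of stress genes in ACT_IL21 against N (adjusted p = 0.0882) and of stress (0.0788), naive (0.0562) and cell cycle genes (0.0513) in ACT_IL21 against ACT.

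Each library was left out in turn, and the lone library left in its pool was assumed to vary like the other pools. ACT against N then had 205 to 526 genes (171 to 365 higher, 34 to 161 lower), ACT_IL21 against N 75 to 728 (61 to 545 and 13 to 183), and ACT_IL21 against ACT 0 to 81 (0 to 29 and 0 to 55). For the 0, without ACT_IL21 replicate 1, limma had 1631 genes at an unadjusted p under 0.05. The F test had 227 to 784, ACT lay between in 73 to 333 and outside in 153 to 468, and shared calls numbered 60 to 280. Lists past the threshold numbered 13 to 15, 11 to 14 and 7 to 12, and 29 of 38 list calls held with each of the 6 libraries left out. Of the genes called with all libraries, 181 of 743, 59 of 677 and 0 of 259 passed each time. The depth of the libraries is unknown, so how far depth limits these counts could not be measured.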

Other observations

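The gene families and marker genes in this part were chosen after seeing the data, and the bounds of the tests were set before the test values were seen. None of the families was tested for enrichment. Of 16 chemokine receptor genes tested, 10 rose and 1 fell in ACT against N, 6 rose and 1 fell in ACT_IL21 against N, and 1 rose and 5 fell in ACT_IL21 against ACT, with no called member changing sign under another scaling. Cxcr5 (chromosome 9, 44511787 to 44561877, minus strand, protein-coding), the receptor that takes T cells into B cell follicles, was at 2.7 ± 1.63 TPM in N, 16.4 ± 1.95 in ACT and 93.5 ± 2.21 in ACT_IL21 (SD, n = 2). By limma it rose at each step, by 2.31 (adjusted p = 0.0083) and then 2.44 (adjusted p = 0.0155) on the log2 scale. Ccr2, Ccr8, Ccr9 and Cxcr6 were among those that fell from ACT to ACT_IL21, Ccr2 from 212 ± 11.5 to 21.1 ± 9.85 TPM. Ccr7, the receptor for lymphoid T cell zones, fell against N in both ICOS+ pools, by -2.22 and -1.44.

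Of 11 ligand genes of the TNF superfamily, 4 were higher and 1 lower in ACT against N, 4 were higher in ACT_IL21 against N, and 2 were higher and 2 lower in ACT_IL21 against ACT, so that 6, 7 and 7 did not pass. Tnfsf11, which encodes RANKL, was at 2.36 ± 1.2, 24 ± 7.88 and 46.3 ± 6.8 TPM in N, ACT and ACT_IL21, and Fasl, a death receptor ligand gene, at 10.1 ± 1.06, 55.4 ± 17 and 11.4 ± 5.02 TPM. Among interleukin genes other than Il21, whose reporter set the gate, Il2, Il4 and Il10 were higher than in N in both ICOS+ pools, and Il4 fell in ACT_IL21 against ACT. Of 14 killer cell lectin-like receptor genes, 8 rose in ACT, 2 rose and 1 fell in ACT_IL21 against N, and 7 fell in ACT_IL21 against ACT. No called member of these families changed sign under another scaling. ACT_IL21 against ACT had 0 genes past the threshold without ACT_IL21 replicate 1 by limma (1631 at an unadjusted p under 0.05) and 5 without ACT_IL21 replicate 2.

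ACT held high levels of genes linked to innate-like T cells. Tcrg-C1, a gamma chain constant gene, was at 327.2 and 226.89 TPM against at most 31.45 elsewhere. Trav11, the segment of the invariant NKT receptor, was at 511.36 and 358.23 TPM against at most 39.05 (ACT_IL21 against ACT, limma adjusted p = 0.109). The similarly named segment Trav11d was at 356.3 and 225.4 TPM in ACT against at most 16.95 elsewhere. By limma Trav11d was higher in ACT than in N (5.19, adjusted p = 7.3e-05) and lower in ACT_IL21 than in ACT (-4.2, adjusted p = 0.0019). The tables argue against natural killer cells, whose receptor gene Ncr1 reached 1.06 TPM at most in ACT, and against CD8 T cells, whose Cd8a and Cd8b1 summed in ACT to 0.282 of the N level, and a sort for CD4 would remove most of either. Invariant NKT cells, some of which carry CD4 and would pass the sort, may contribute: Trbv13-2, Trbv29 and Trbv1 made up 45.2% and 29.3% of all Trbv TPM in ACT against 23.6% to 25.4% in the other libraries. Of these segments Trbv29 was highest in both ACT libraries (47.7 and 30.25 TPM), while Trbv13-2 and Trbv1 overlapped the other pools. Gamma-delta T cells, most of which a sort for CD4 would remove, stay open. The gamma constant genes Tcrg-C2 (293.94 and 221.8 TPM) and Tcrg-C4 (275.04 and 174.05) were high in ACT too, against at most 35.69 and 31.74 elsewhere. The gamma variable segment Tcrg-V4 was listed at 0 in both N libraries, at 42.77 and 20.89 TPM in ACT and at 2.99 and 3.75 in ACT_IL21. By limma Tcrg-C1 was also higher in ACT_IL21 than in N (2.22, adjusted p = 0.00234). The delta variable segments Trdv1 (1.72 and 4.51 TPM in ACT, 6.94 to 17.14 elsewhere) and Trdv2-2 (0 and 0) were not higher in ACT. Trdv2-1 and Trdv5 were at 0 in ACT and reached 0.9 and 2.37 TPM in N. However, Trdv4 was at 0 and 2.32 TPM in ACT and at 0 elsewhere. Gamma-delta T cells can use other segments, and 0 symbols of the delta chain constant region were in the table used here.

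Foxp3 and Il2ra were lower in ACT_IL21 than in N and ACT. Scaling between libraries could move these values little, since the median-of-ratios factors lay between 0.9533 and 1.063. The log2 fold change of Foxp3 against ACT was at most -4.31 under other scalings. The bound set for scaling as the cause was out of reach, so this was no test of it. A smaller share of regulatory T cells among ACT_IL21 cells may contribute and cannot be told apart from lower levels within the cells. The other 8 regulatory genes had a median of -0.81, 6 were lower, and Ikzf4 (-2.49) and Tnfrsf18 (-1.23) passed the threshold, while Ctla4 and Nrp1, which activated and follicular cells also express, had values of 0.05 and 0.24. That median lay between the bounds set for and against this explanation.

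Replicates 1 and 2 of N and of ACT differed in the same direction, with a correlation of 0.359 across the 8851 genes used for this test, which are fewer than the 13311 tested. A transcript length trend is argued against as the whole cause, since removing it left 0.352. GC content stays open, since removing its trend left 0.215, which lay between the bounds set for and against it. No biological explanation was tested. Haemoglobin RNA also differed by replicate number, with Hbb-b1 at 106.1 and 27.22 TPM in N, 101.23 and 41.4 in ACT, and 225.03 and 73.09 in ACT_IL21 for replicates 1 and 2.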
